A study of Mus musculus with 2 samples.

How the data were processed

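RNA from adipose tissue of C57BL/6 mice, an inbred laboratory strain, was measured on 2 Affymetrix mouse expression arrays. One array held RNA pooled from 3 mice on a normal diet (CE-2 chow) and the other held RNA pooled from 3 mice on a high fat diet (HFD32), with feeding from 6 to 18 weeks of age, a span of 12 weeks. The fat depot and the sex of the mice are not given in the sources used here. Labelling was with biotin by the manufacturer's protocol, per the labels' protocols.

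The deposited values are log2 signals, 1 for each of 45101 probe sets on each array, which the authors made with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the submitters' processing notes. The version of RMA and the annotation used with it are not given in the sources used here. The log2 scale was taken from the values, which ran from 2.04 to 14.28 on the normal diet array and from 2.06 to 14.21 on the high fat diet array. The medians over each whole column were 5.47 and 5.40. After sorting, the 2 columns differed nowhere by more than 0.14, so their distributions had already been made nearly equal. Such a step assumes that most genes do not differ and removes any change in total RNA. On 1509 probe sets (3.35%) both arrays had exactly the same value. RMA also compresses differences at the dim and the bright end of the scale, and the scanner files were not used here.

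Probe sets were named from GEO's platform annotation, which can be old, and symbols were looked up again by Entrez gene ID in a RefSeq table for the mouse assembly GRCm38.p6. Of these, 34958 had 1 gene symbol and 932 had several, while 9160 probe sets other than controls had none. The array holds 64 control probe sets, 51 with no symbol and 13 counted among those with 1 symbol, and all were left out of the gene comparison. The ID of 34754 probe sets with 1 symbol was found in the RefSeq table, which changed no symbol. Only probe sets with 1 symbol were used for genes, 18193 in all. A list member without such a probe set was not analysed here. No coordinates are given, since the values carry no genome build.

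The choices of the floor, the fold, the lists, the rule for named genes and most alternatives were made before the data were examined. A gene was represented by its probe set with the highest mean of both arrays. It entered the comparison if that mean was at or above the median of all non-control probe sets, 5.44 on the log2 scale (the floor), which left 11778 genes. The difference is the high fat diet log2 signal minus the normal diet log2 signal, and a difference of 1 is a 2-fold ratio of signals. Background was taken from 83 probe sets of sensory receptor genes (olfactory, vomeronasal and bitter taste receptors), whose median was 3.07 and 3.23 and whose 95th percentile was 4.92 and 4.95 on the normal and the high fat diet array. Where the dimmer array lay under that 95th percentile, the ratio is a bound, computed against the 95th percentile and written "at least".

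With 1 array per diet, no test between the diets was possible, and no p-value, SD or SE between samples is given. The number of arrays limits the precision. Pooling averages over animals and leaves their spread unknown. Error within the arrays was estimated from genes with several probe sets above the floor (5131 genes). The SD between probe sets of 1 gene was 0.27 on the log2 scale. In 3105 genes with 2 such probe sets the gap between both differences had a median of 0.18 and a 95th percentile of 0.70. Among 240 genes past 2-fold with several probe sets, the other probe sets pointed the opposite way in 5. This error covers the probes alone, not animals, dissection, RNA or hybridisation.

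For 41 gene lists, 7 of them primary, the median difference of the members above the floor was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay above 97.5% or below 2.5% of the random medians, which by chance alone would hold for about 2.05 of 41 lists. Members of 1 list are often expressed together and lists share members, so this describes the 2 arrays and is no test. The procedure was tested on simulated data for this comparison. Over 11778 genes, with a noise SD of 0.34, all 200 genes shifted by 2 on the log2 scale were recovered along with 38 unshifted ones. Of 41 unshifted random lists 2 stood apart, and with a shift of 0.5 on the log2 scale 40 did. The simulated noise was drawn independently for each gene from a normal distribution, so these counts do not estimate false calls in the real data.

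Named genes were chosen by rule. They are the 12 highest and 12 lowest differences among genes with a proper symbol whose other probe sets agreed in sign, up to 4 members of each list (the 3 farthest in the direction of the list's median and the 1 farthest the other way), and 13 genes always reported. Genes named outside the rule are said to be. Alternatives were other floors, other scalings of the arrays (lowess with a span of 0.3, quantile normalization, centring), the median of a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, and other folds. Leaving out the genes of other tissues was added after the data were seen, as were 4 lists of hepatocyte and epididymis genes, the percentiles under the alternatives, the medians with signals under background raised to it and the adipocyte median below a level of 12. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.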

Results

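Gene expression in adipose tissue was compared between C57BL/6 mice fed a normal diet (CE-2) and mice fed a high fat diet (HFD32) to induce obesity, from 6 to 18 weeks of age. Each diet was measured on 1 array of RNA pooled from 3 animals. There are therefore no replicates and no replicate check, and every difference below compares 2 pools. Differences are log2 signal on the high fat diet array minus log2 signal on the normal diet array. The number of arrays limits the precision, and the only error available is the SD of 0.27 on the log2 scale between probe sets of 1 gene.

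Across 11778 genes above the floor, 386 (3.28%) were at least 2-fold higher and 388 (3.29%) at least 2-fold lower on the high fat diet array. At 8-fold the numbers were 22 higher and 70 lower. The median gene differed by 0 and the quartiles lay at -0.23 and 0.23. With the floor raised to the 75th percentile of the probe sets, 190 genes were higher and 132 lower.

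The genes that stood highest on the high fat diet array belonged to several groups. Tph2, which encodes the tryptophan hydroxylase of neurons, went from a level of 3.36 to 10.38, at least 44.1-fold higher. Ubd, which encodes the ubiquitin-like modifier FAT10, had 6.14 and 12.56, a ratio of 85.7. Atp6v0d2, a subunit of the lysosomal proton pump found in macrophages and osteoclasts, was 19.3-fold higher, and Saa3, an acute-phase protein made in inflamed fat, was 14.5-fold higher. Genes of the epididymis were among the same 12, with Gpx5 16.4-fold higher and Lcn8, Adam7 and Cst12 higher by at least 21.8-fold, 10.5-fold and 9.78-fold. The bound of Lcn9, another of them, lay between those of Lcn8 and Adam7. The others were Lipf, a gastric lipase, Slc5a7, the choline transporter of cholinergic neurons, and Vsig8, higher by at least 10.2-fold, 6.90-fold and 5.91-fold.

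The 12 genes that stood lowest were all transcripts abundant in liver. Serpina1c, an alpha-1-antitrypsin, had a level of 12.38 on the normal diet array and 5.69 on the high fat diet array, 103.8-fold lower. Ttr, which carries thyroid hormone in blood, was 82.6-fold lower, Fabp1, the liver fatty acid binding protein, 49.8-fold, Serpina1b 47.7-fold and Apoa2, a lipoprotein component, 40.7-fold. Cyp3a11, Fga, Fgg, Bhmt, Pzp, Serpinc1 and Cps1 were near background on the high fat diet array and were lower by at least 32.9-fold, 24.9-fold, 32.3-fold, 28.7-fold, 29.4-fold, 23.6-fold and 17.0-fold. The difference of Ttr was -6.37, and -4.03 without probe sets that can match several transcripts. Without 139 genes of lists of liver and other tissues, a setting chosen after seeing the data in which some lists were drawn from the top genes themselves, 377 genes were at least 2-fold higher and 297 at least 2-fold lower.

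**Figure D1:**
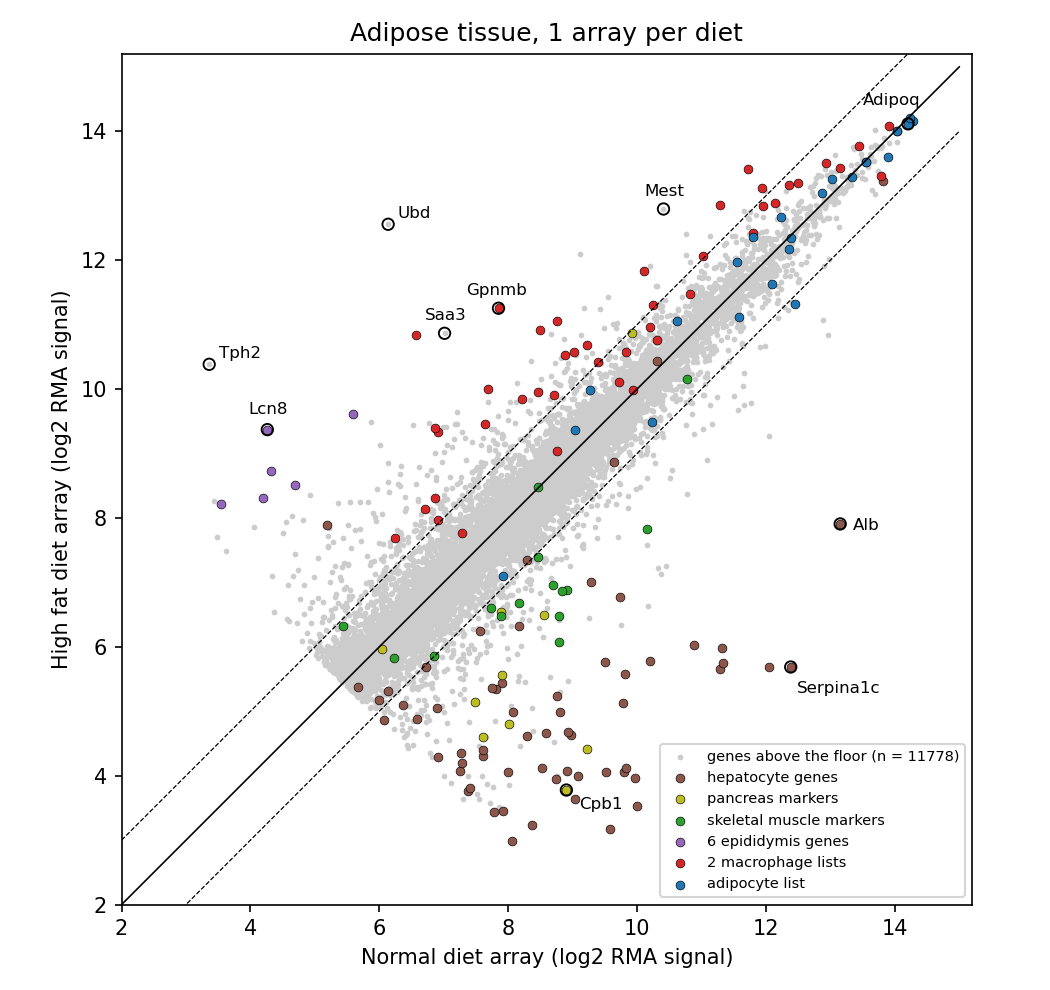
Log2 signal of 11778 genes on the normal diet array (horizontal axis) and on the high fat diet array (vertical axis), 1 point per gene, with gene groups in colour, named genes ringed, a solid line of equal signal and dashed lines at 2-fold. Macrophage genes (red) lie mostly above the line of equal signal and adipocyte genes (blue) lie along it. Hepatocyte and pancreas genes lie mostly below it, such as Cpb1, at least 15.5-fold lower on the high fat diet array. Of the hepatocyte genes, 27 were taken from the lowest differences, and the 6 epididymis genes from the highest. The places of these genes follow from that choice.

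Macrophage markers were higher on the high fat diet array throughout. All 25 measured markers had a positive difference and 15 of them were at least 2-fold higher, with a median of 1.05, above all 10000 random lists. Cd68, a lysosomal glycoprotein of macrophages, was 4.91-fold higher, and Adgre1, the classical surface marker of mouse macrophages, was 3.13-fold higher. Ms4a7 (1.83) and the signalling adaptor Tyrobp (1.72) were also higher, while Cd163, a haemoglobin scavenger receptor of resident macrophages, differed by 0.04 and the mannose receptor Mrc1 by 0.46, both named outside the rule. Genes of lipid-associated macrophages, which take up lipid around dying adipocytes, had a median of 1.03 over 20 genes, of which 10 were at least 2-fold higher and 0 lower. They included Atp6v0d2 (4.27), Gpnmb (3.40), the lipid receptor Trem2 (2.53), Mmp12 (2.43, named outside the rule) and Itgax, which encodes CD11c, at 5.35-fold, whereas Apoe had -0.49. The 2 lists share no gene, and the second also lay above all random lists. On the same arrays the adipocyte list had a median of -0.04 and some markers of other tissues were lower on the high fat diet array, with medians of -2.34 for pancreas, -1.41 for skeletal muscle and -2.47 for 35 hepatocyte genes of a list added after the top genes were seen, while epididymis and testis markers had 1.56.

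Lysosome genes had a median of 0.58, with 23 of 25 higher and 7 at least 2-fold. The cathepsins Ctsk (1.63) and Ctss (1.57) followed Atp6v0d2, and Lamp2 had -0.15. Genes of MHC class II, which present antigen to T cells, had a median of 0.71 with 6 of 7 higher, among them H2-DMa (0.81) and Ciita (0.76), the master regulator of the class. H2-Ab1 had 0.77, and 1.16 without probe sets that can match several transcripts. Dendritic cell markers had a median of 0.38 over 10 genes, 9 higher and 1 lower, and 0.92 over 6 genes with the higher floor. Itgax (2.42), also a gene of the lipid-associated macrophage list, led them, with Cd83 at 1.19 and Irf8 at 1.17. Zbtb46 had -0.02. Complement genes had a median of 0.75 over 13 genes, 9 higher and 4 lower. Itgam and, named outside the rule, C1qa, C1qb and C1qc also stand in the macrophage marker list, and Itgax in that of lipid-associated macrophages. The receptors Itgax (2.42), C3ar1 (1.74) and Itgam (1.44) were higher, while Cfi (-1.49), a complement inhibitor made mainly in liver, was lower, as hepatocyte transcripts were. The percentiles among random lists were 100 for lysosome and complement genes, 99.98 for MHC class II and 99.6 for dendritic cell markers.

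Chemokines, cytokines and acute-phase genes had a median of 0.60 over 25 genes, with 21 higher, 7 of them at least 2-fold, and a percentile of 100. Saa3 (3.85) led the group, followed by the interleukin 1 receptor antagonist Il1rn (2.62) and the monocyte attractant Ccl2, which was 5.41-fold higher. Tnf differed by 0.53 and Il18 by -0.37. Ccl3, Cxcl2, Il1b, Il6, Il10 and Nos2 lay below the floor and were not compared. Interferon response genes stayed among the random lists, with a median of 0.10, and so did markers of T and NK cells (0.16), of B and plasma cells (-0.16) and of neutrophils, eosinophils and mast cells (-0.26). Single members differed more, such as the interleukin 7 receptor Il7r (3.13), the B cell antigen Ms4a1 (-1.13), and S100a8 (2.11) against S100a9, which was at least 2.80-fold lower. The medians of these 3 marker lists each took the other sign under 1 alternative. In the same order they were -0.06 without probe sets that can match several transcripts, 0.45 over 3 genes with the higher floor and 0.16 with no floor. Other settings put each of the 3 lists outside the random lists. With no floor, T and NK cells had 0.24 at percentile 98.6 and B and plasma cells -0.32 at percentile 0.21. B and plasma cells also had -0.40 at percentile 0.76 with the median of each gene's probe sets. Markers of neutrophils, eosinophils and mast cells lay at percentile 2.49 with the floor at background.

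Cell cycle genes were higher on the high fat diet array in 22 of 22 cases, 15 of them at least 2-fold, with a median of 1.10 and a percentile of 100. Birc5 (2.11), Cdk1 (2.07), Ube2c (1.74) and, named outside the rule, Mki67 (1.42), genes of mitosis and proliferation, were among them. With the higher floor, which keeps only 3 of these mostly dim genes, the median was 0.54 at percentile 97.6. Beside them, macrophage markers had a median of 1.05 and lipid-associated macrophage genes 1.03.

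Adipocyte identity genes and targets of PPAR gamma, the regulator of fat cell differentiation, went both ways. The median was -0.04 over 22 genes, at percentile 33.8, with 8 higher and 14 lower. Many of these genes lie near the top of the scale, where differences are compressed, and the 9 with a mean level below 12, a limit set after seeing the data, had a median of -0.46 at percentile 0.04, with 4 higher and 5 lower. Adipoq, which encodes adiponectin and had levels of 14.21 and 14.12 near the highest values of the arrays, differed by -0.09, Pparg by -0.47 and the insulin-responsive glucose transporter Slc2a4 by -0.74, while Pck1, an enzyme of glyceroneogenesis, differed by -1.13 and Cebpb by 0.72. Lep, the satiety hormone of fat, was 2.11-fold higher, with levels of 11.99 and 13.07. Mest, which marks expanding adipocytes, was 5.22-fold higher, with levels of 10.41 and 12.79. It belongs to the adipocyte expansion genes, whose median was 0.58 at percentile 100 with 9 of 11 higher, including the Wnt inhibitor Sfrp5 (2.19). Part of this list is expressed by other cells, such as Trem2. Adipokines and other secreted factors had a median of -0.09 and a mean of 0.11, hence opposite signs, at percentile 13.2. Agt (-1.60), angiotensinogen, which liver also makes, was lower, as hepatocyte transcripts were.

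Genes of lipid synthesis were lower on the high fat diet array. Lipogenesis genes had a median of -0.30 over 25 genes, below all random lists, with 17 lower and 3 of them at least 2-fold. Acaca, the enzyme of malonyl-CoA synthesis, had -1.61, Mogat1 -1.55, the carbohydrate sensor Mlxipl -1.34 and the fatty acid synthase Fasn -0.62, against 0.92 for Scd2. The desaturase Scd1 had levels of 14.17 and 14.15, so close to the highest values of the arrays that its difference cannot be read. Without probe sets that can match several transcripts the list's median was -0.46. Liver expresses most of these genes as well, and the 35 hepatocyte genes had a median of -2.47.

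Cholesterol synthesis and uptake genes stood in the other direction, with a median of 0.79 over 19 genes at percentile 100. In this group 16 genes were higher, 5 of them at least 2-fold, including Dhcr7 (1.54), Lss (1.29) and Nsdhl (1.06), enzymes of the later steps of the pathway, while Fdft1 had -0.58. The median was 0.52 without probe sets that can match several transcripts.

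Mitochondrial genes were slightly and broadly lower. Genes of the respiratory chain and the TCA cycle had a median of -0.15, with 37 of 46 lower, 0 of them by 2-fold or more, at percentile 0.05. Pdha1, of pyruvate dehydrogenase, had -0.58, Uqcrc2, of complex III, -0.42 and Sdha, of complex II, -0.36, against 0.46 for Dlat. Genes that break down branched-chain amino acids had a median of -0.38 with 16 of 20 lower, below all random lists. Ivd had -1.03 and Acadsb -0.74, both acyl-CoA dehydrogenases. The cytosolic transaminase Bcat1 was at least 4.12-fold higher on its brighter probe set, while its other probe set differed by 1.23. Brown and beige adipocyte genes had a median of -0.84 over 14 genes, 6 higher and 8 lower, also below all random lists. Ucp1, the uncoupling protein of heat production, was 2.39-fold lower, Fabp3 had -1.67 and Slc27a2, a fatty acid transporter that liver also expresses, was at least 10.8-fold lower, while the potassium channel gene Kcnk3 had 0.58. With no floor this median was -0.08, at percentile 11.0 and so among the random lists. Beside these groups, skeletal muscle markers, which come with many mitochondria, had a median of -1.41, and the 35 hepatocyte genes had -2.47.

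Other metabolic lists lay among the random lists. Fatty acid oxidation genes had a median of -0.003 and a mean of 0.005, hence opposite signs, at percentile 48.2, with Ppargc1a at -0.95 and Cpt1a at 0.84. Lipolysis and lipid droplet genes had 0.13 (0.21 with the median of each gene's probe sets, which lay at percentile 97.8 and so stood apart), with the droplet coat gene Plin2 at 1.18. Glucose transport and glycolysis genes had 0.09, with the pyruvate dehydrogenase kinase Pdk4 at 1.39. Insulin signalling genes had -0.16 at percentile 3.17 (-0.04 with the median of each gene's probe sets), with the receptor substrate Irs1 at -1.13, Pik3r1 at -0.95 and the insulin receptor Insr at -0.65.

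Collagen and extracellular matrix genes had a median of 0.36 over 42 genes at percentile 100, with 32 higher and 5 at least 2-fold. The inhibitor of matrix proteases Timp1 (2.35), the protease Mmp3 (2.19) and periostin, Postn (1.29), were higher, as were, named outside the rule, Lox (0.96), which crosslinks collagen, and Col6a2 (0.90), while Mmp9 had -1.69. Preadipocyte and fibroblast markers had a median of 0.07 and a mean of -0.002, and a median of -0.20 with the higher floor, at percentile 1.43 and so below the random lists. Endothelial and angiogenesis genes were lower in 20 of 22 cases, with a median of -0.45 below all random lists. Angpt1 had -1.69 and Vegfa -1.02 (-0.35 on its other probe set), both growth factors for vessels, against 0.42 for Nos3. Beside them, smooth muscle and pericyte markers had a median of -0.96, mesothelium markers -0.88 and skeletal muscle markers -1.41.

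Endoplasmic reticulum stress genes had a median of 0.21 at percentile 98.8, with the stress transcription factor Atf3 at 2.71 and Sdf2l1 at 1.31. With the higher floor the median was 0.13 at percentile 91.9, so the list no longer stood apart. Antioxidant and detoxification genes had a median of -0.17 at percentile 0.51. The glutathione transferases Gsta4 (-1.99), Gsta3 (-1.90) and, named outside the rule, Gstt1 (-1.64) and the secreted peroxidase Gpx3 (-1.81) were lower, and Hmox1, the haem oxygenase, was higher (1.39). Liver is rich in glutathione transferases, and hepatocyte transcripts were lower too. Circadian clock genes were lower in 14 of 15 cases, with a median of -0.32 at percentile 0.29, with Dbp at -0.81 and Nr1d2 at -0.71 against 0.76 for Nfil3. The hour at which tissue was taken is not given in the sources used here. Immediate early genes, which respond to handling of tissue, had a median of -0.05 and a mean of 0.19, hence opposite signs, at percentile 26.4. Of these 20 genes, 9 were higher and 11 lower. At 2-fold 3 were higher, among them Atf3 (2.71) and Egr2 (2.02), and 0 were lower.

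Markers of tissues next to fat differed strongly between the arrays. Pancreas markers had a median of -2.34, with 8 of 10 at least 2-fold lower on the high fat diet array. The digestive enzymes Cpb1, Cela2a and Cpa1 were lower by at least 15.5-fold, 19.3-fold and 8.39-fold, while Cela1 had a difference of 0.95. Skeletal muscle markers had -1.41, with the fast myosin Myh4 at -2.72 and myoglobin, Mb, at -2.31, against 0.89 for Ryr1. Smooth muscle and pericyte markers had -0.96, with Cnn1 at -3.54 and Myh11 at -3.25, and mesothelium markers had -0.88, with the keratins Krt8 (-1.46), Krt18 (-1.41) and Krt19 (-1.37). These 4 lists lay below all random lists. Epididymis and testis markers had a median of 1.56 over 8 genes that went both ways, 4 higher and 4 lower, with the sperm gene Tnp1 at least 6.05-fold lower. Over the alternatives this median ran from 0.11 to 3.82, and with no floor it lay at percentile 77.4, among the random lists. With signals under background raised to it, the median was 1.34. Mammary and skin epithelium markers (-0.15, with 0.09 under no floor, -0.31 with the median of each gene's probe sets and -0.32 without probe sets that can match several transcripts), erythroid markers (-0.35, and -0.32 at percentile 1.06 with no floor) and nerve and Schwann cell markers (0.15) lay among the random lists.

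Ribosomal protein genes, with a median of -0.07, and commonly used reference genes, with a median of 0.06, also lay among the random lists, though the reference gene Gusb, a lysosomal enzyme, had 1.25. Signal of the 3' end over the 5' end, a sign of RNA quality, was alike on both arrays. For Actb it was 0.63 on the normal diet array and 0.49 on the high fat diet array, and for Gapdh -0.05 and -0.12. In total 13 lists stood above and 11 below the random lists, 17 lay in between, and about 2.05 outside would come by chance. Lists share members and genes of a list are expressed together, so these percentiles describe the 2 arrays only.

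**Figure D2:**
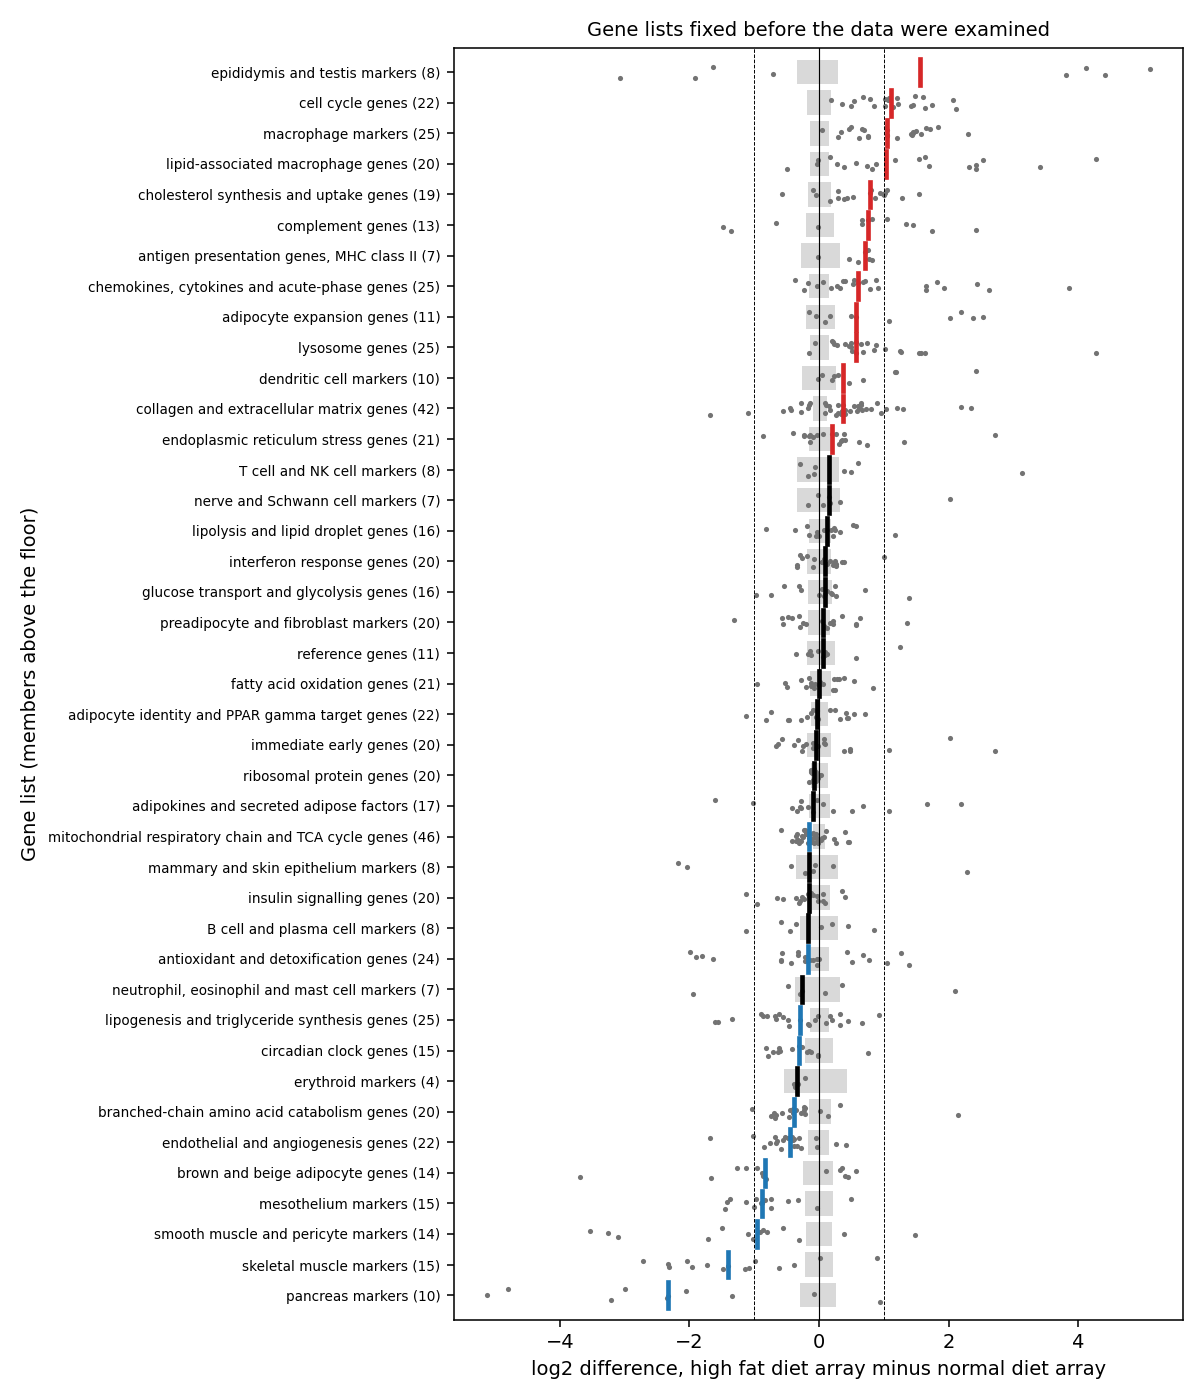
Log2 difference (high fat diet minus normal diet, horizontal axis) in 41 gene lists, 1 row per list. Small grey points are the member genes above the floor, and a vertical bar marks the median of each list. A grey band covers the central 95% of the medians of 10000 random lists. Bars are red above the band, blue below it and black inside it. Cell cycle genes have a median of 1.10, macrophage markers 1.05 and pancreas markers -2.34.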

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

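The tests of scaling, dilution and macrophage make-up were chosen only after their results were seen. The scaling test replaced a rescaling of columns that were nearly equal already and could not have come out otherwise. The rule of the make-up test was changed after its result was seen, which moved that explanation from excluded to open. Also chosen then were the medians with signals under background raised to it. The lists of held-out hepatocyte and epididymis genes were written after the top genes were seen and before the values of their members were looked at.

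Probe sets with no gene symbol or several symbols were not used for genes. Of 2430 such probe sets above the floor, 60 (2.47%) were at least 2-fold higher and 220 (9.05%) at least 2-fold lower on the high fat diet array. The shares of genes were 3.28% and 3.29%, but a gene counts once, by its brightest probe set, so the units differ. The labelling controls, bacterial transcripts usually added to the RNA before labelling, had a median difference of 0.34, and all 24 were higher on the high fat diet array, by 0.09 to 0.43. The hybridisation controls, usually added after labelling, had a median difference of 0.03.

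Hepatocyte and pancreas transcripts were high on the normal diet array, among them Alb, named after its value was seen, with levels of 13.15 and 7.91. Scaling of the arrays is argued against, since it would move genes of equal brightness alike, and the median of 60 held-out hepatocyte genes lay -1.95 from that of random lists matched on mean expression, whose SD was 0.05. RNA of liver in the normal diet pool may explain the hepatocyte part, since as deposited the held-out genes had a median of -1.91, below all random lists (-1.49 with signals under background raised to it), with 56 lower and 43 of them at least 2-fold. Of the 60 genes, 23 lay above background on the high fat diet array too, so some may be expressed in fat, and 0 stand in the lists fixed beforehand. A diet effect on these transcripts stays open as untested, because each diet is 1 pool, and no held-out list was run for pancreas.

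Epididymis transcripts, led by Lcn8, were high on the high fat diet array. RNA of epididymis in that pool could be the source, but 19 held-out epididymis genes had a median of 0.18 at percentile 94.2, with 12 higher, 6 lower and 0 at least 2-fold higher. Since 14 of the 19 lay under background on both arrays, this median says nothing about the source. The 5 above the floor were all lower on the high fat diet array, with a median of -0.67, among them, named after their values were seen, Spink8 with levels of 10.16 and 7.57 and Defb42 with 9.86 and 8.34. The 5 genes are too few to decide, so the source stays open, and a diet effect was not tested.

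Macrophage markers were higher on the high fat diet array. Dilution of fat RNA by other tissues on the normal diet array would raise adipocyte genes alike, if the diet itself left them unchanged. The adipocyte median was -0.036 with a spread of 0.07 among random lists, below the limit of 0.52 set for this test. So was the -0.46 of the 9 adipocyte genes away from the top of the scale, where differences are compressed. Under both conditions the values argue against dilution as the whole cause. Neither condition was tested with 1 pool per diet, so dilution is not excluded. More macrophages of unchanged make-up may account for part of the rise in macrophage markers. The differences of 21 markers below a level of 12 had an SD of 0.56, against 0.27 between probe sets of 1 gene, but no marker lay below 0, and markers that other cells express can differ unevenly. Both this and a change of the macrophages with the diet stay open.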

How the results depend on the processing

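The setting without genes of other tissues and the list percentiles under each alternative were chosen after the results were seen. That setting gave 377 genes higher and 297 lower, within 1.5 times the reported counts. It left out 139 listed genes only, 91 of them at least 2-fold lower. Other genes that liver also makes, such as Agt, stayed in. The counts therefore do not show how many of the remaining differences are free of RNA of other tissues. The floor at the 75th percentile gave 190 genes higher and 132 lower, since fewer genes are compared. By construction the size of 1.5-fold gave 966 and 1004 and the size of 3-fold gave 138 and 182. The median of chemokines, cytokines and acute-phase genes was 0.70 with the 75th percentile floor and 0.69 without _x_at and _s_at probe sets. That of lipid-associated macrophage genes was 1.18 with the median of probe sets and 0.88 without _x_at and _s_at probe sets, which also gave -0.46 for lipogenesis genes. For these list medians the cause was not tested. Of 356 list medians under alternatives, 30 moved by more than 1 SD of random lists. Of 1355 differences of named genes, 14 moved by more than the SD between probe sets. Many of these 1355 could not move, because a gene keeps its brightest probe set under every floor and when genes of other tissues are left out. The median of probe sets can move only genes with several probe sets, so the 14 understate how far named genes depend on the processing. Of the lists that stood apart, brown and beige adipocyte genes and epididymis and testis markers lay among the random lists with no floor, and endoplasmic reticulum stress genes with the 75th percentile floor. Brown and beige adipocyte genes, epididymis and testis markers and pancreas markers had too few members above the 75th percentile floor for a median there. Among the values computed, no list that stood apart and no named gene past 2-fold took the other sign. Setting the median difference to 0 moved nothing, since it was 0 already, and no scaling moved the median of all genes by 0.1 or more. The offset for linear values was not run because the values are log2, and leaving out an array is not possible with 1 per diet. No paired analysis was possible because each diet has 1 array. Signal near background limits the dim genes, whose ratios are bounds.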

Other observations

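All genes in this part were chosen after their values were seen, and so were the lists of hepatocyte and epididymis genes seen.

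Among 1817 bright genes, with a mean level of 10 or more, several outside the lists differed strongly. Fgf13, a fibroblast growth factor homologue that binds sodium channels, had levels of 9.11 and 12.10, and its probe sets had a median difference of 3.55. Mtarc1, a mitochondrial amidoxime reductase, was higher by 2.08, Pcolce2, which aids collagen maturation, by 1.88, Mpeg1, the perforin-like protein of macrophages, by 1.81, and Prps1, an enzyme of nucleotide synthesis, by 1.71. On the lower side stood the muscle tropomyosin Tpm2 (-2.78), Thbd (-1.99), the thrombomodulin of vessel walls, and the methyltransferase Inmt (-1.90).

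Of the hepatocyte genes, 27 taken from the lowest differences had a median of -5.13, and 35 held-out genes above the floor had -2.47. With signals under background raised to it, these medians were -4.56 and -2.31. The coagulation factor gene F7 was 1 of 2 of these that were higher on the high fat diet array, with levels of 5.19 and 7.90. The 6 epididymis genes taken from the highest differences had a median of 4.27, or 3.70 with signals under background raised to it, and 5 held-out ones above the floor had -0.67. Rnase10, one of the 6, was at least 12.1-fold higher.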
